A study of Homo sapiens with 2 samples.

How the data were processed

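RNA from HCT116 cells, an established human colorectal carcinoma line, was compared between cells carrying a lentiviral scrambled control and cells carrying a lentiviral short hairpin against ID4. Each of the 2 groups had 1 library. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a strand-specific Agilent SureSelect kit for Illumina sequencing. The submitters' processing notes name bcl2fastq, Trimmomatic 0.32, HISAT2, Cufflinks 2.2.1, Cuffdiff and the genome build GRCh38.p10, without saying which of them made the deposited values. How strand was handled in counting is not given in the sources used here, so an antisense gene or a gene overlapping another can hold reads of its partner.

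The authors deposited 1 table of 60483 genes with a value for each library, and per the file headers the unit is TPM. The deposited values are CPM instead (reads of a gene scaled to a library total of 1000000), as the values themselves show. In each library, 100% of the values above 0.001 were whole multiples of the smallest of them, within a tolerance of 1e-06 of a read, whatever the length of the gene. Those values summed to 1000000, so no division by gene length had been made, and 0.001 stood in for 0 reads. The step was 0.0478 CPM per read in the scramble library and 0.0399 CPM in the shID4 library, which gives 20921477 and 25067555 counted reads. The placeholder was read as 0. Because gene length was not divided out, levels of different genes within a library reflect length as well as abundance, while the ratio of a gene between libraries does not. Of the rows, 3615 had no gene name and 27 had a whole number in place of a name, which is what a spreadsheet leaves when it reads a symbol as a date. Rows without a name held 0.0561% of the scramble reads and 0.0562% of the shID4 reads. They were kept in the totals, since the deposited scaling includes them, and were named by identifier.

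The gene lists, the filter, the rule for named genes and all settings not stated below as added were chosen before the data were examined. The plan had assumed FPKM values, because the processing notes name Cufflinks. The same numerical limits were applied to CPM, and the filter, the pseudocount and the counts of genes that rest on them therefore differ from what FPKM values would give. With 1 library per group there is no replicate spread, so no test between the groups, no p-value and no standard error is given. The log ratio of each gene was log2((shID4 CPM + 1)/(scramble CPM + 1)), which understates the difference of genes with low levels. Genes with a mean of at least 1 CPM over both libraries were used, and 15269 passed this filter. A gene was called higher or lower in shID4 when the log ratio was at least 1 or at most -1, a 2-fold rule of size. Folds printed beside levels are plain ratios of CPM without a pseudocount. Their 95% intervals are exact binomial intervals of the reads of a gene in 1 library given its reads in both. They cover counting error only and leave out the variation between cultures. Each read is taken as independent, so reads copied by PCR can make them too narrow. A count of 0 allows up to 3 reads, or 0.143 CPM in the scramble library and 0.120 CPM in the shID4 library.

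A set of 37 gene lists (pathways, complexes and markers of other cell types) was summarised by the median log ratio of the members past the filter. The percentile of that median among 10000 random lists of the same size, matched on 20 bins of mean expression, was given for the 33 lists with at least 5 such members. A list stood apart below the 2.5 or above the 97.5 percentile. About 1.65 lists would be outside these limits by chance if the genes of a list varied independently. Genes of a pathway can vary together and some lists share members, so more lists than that can stand apart between any 2 cultures. The percentile describes these libraries only. Random lists were matched on expression and not on GC content. Named genes were the 4 ID genes, the 15 highest and the 15 lowest log ratios among genes with a mean of at least 5 CPM that carry a gene symbol, up to 4 members of each list with the largest absolute log ratio, and the reference genes. Some genes that this rule names are not reported here. Other genes named in the text were chosen after their values were seen. A further 6 families (cytosolic and mitochondrial aminoacyl-tRNA synthetases, MHC class II, hemidesmosome and laminin genes, serine and one-carbon enzymes, and keratins) and the BMP ligands were listed after the ranked genes had been seen.

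Coordinates, GC content and transcript length came from GENCODE 29 on GRCh38, matched by gene identifier for 56753 genes of the table and for 99.4% of the genes past the filter. The longest transcript stood for each gene. Alternatives were a pseudocount of 0.1 or 5 CPM, no filter or a mean of at least 5 CPM, a 1.5-fold or 4-fold rule, centring on the median, a common total, scaling by a trimmed mean of log ratios (30% of log ratios and 5% of abundances trimmed at each end), and random lists not matched on expression. Removal of a smooth trend on GC content and transcript length (lowess with a fraction of 0.3), omission of mitochondrially encoded genes from the totals, and omission of members shared between lists were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used.

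The 2-fold rule was tested on simulated reads for all 60483 genes at the depths and mean levels of the scramble and shID4 libraries, with 200 genes changed by known folds. After simulation 15265 genes passed the filter, 193 of them changed. The 2-fold rule called 63 of 66 genes changed 6-fold, 61 of 67 changed 3-fold and 0 of 67 changed 1.5-fold. Counting error alone put 0 of the other 15072 genes past the rule. List percentiles were tested on the log ratios of the 15269 genes of the real libraries. Of 200 random lists of 20 genes, 8 stood apart, and all 20 lists raised 1.5-fold did. Both results largely follow from the construction. The random lists came from the same log ratios as the lists they were set against, and the added shift was wide of the random band. They check the calculation and do not cover genes that vary together or variation between cultures. The counting interval covered the true ratio in 97.1% of 2000 draws with 10 and 8 expected reads.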

Results

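Gene expression was measured by RNA sequencing in HCT116, a human colorectal carcinoma cell line, after lentiviral delivery of a scrambled control hairpin or of a short hairpin against ID4. The data comprised 1 scramble library of 20921477 counted reads and 1 shID4 library of 25067555 counted reads. Reads were found for 30168 and 31063 genes, respectively. Levels are given in CPM, the reads of a gene scaled to a library total of 1000000, with 95% intervals that cover counting error only. With 1 library per group, no difference given here has a replicate check. The comparison addresses how gene expression differs between cells carrying the hairpin against ID4 and control cells.

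ID4, the targeted gene, encodes a helix-loop-helix protein that lacks a DNA-binding domain and pairs with basic helix-loop-helix factors (chromosome 6, positions 19837386 to 19840684, GRCh38). It was lower in the shID4 library, at 0.199 CPM (5 reads) against 0.621 CPM (13 reads), a 3.12-fold difference with an interval of 1.04 to 11.2. Both values lay under the filter of 1 CPM. The direction was that of the label, but the lower end of the interval, which covers counting error only, was close to 1. At this depth neither the direction nor the size of the difference is well determined. The 3 paralogs of ID4, which are far more abundant in these cells, had ratios below 0 as well. ID3 (chromosome 1, 23557918 to 23559794) stood at 32.5 CPM in shID4 against 125 CPM in scramble, 3.83-fold lower (3.54 to 4.15). ID2 (chromosome 2, 8678845 to 8684453) was 2.13-fold lower (1.996 to 2.27), at 57.5 against 122 CPM. ID1 (chromosome 20, 31605283 to 31606515) was 1.82-fold lower (1.76 to 1.88), at 226 against 410 CPM, and did not reach the 2-fold rule. The median log2 ratio of the 3 ID genes past the filter was -1.08.

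SLC7A11, ASNS and CHAC1 had the highest log2 ratios among genes with a mean of at least 5 CPM, and ALPP, AFAP1L2 and KRT7 had the lowest. SLC7A11, the cystine and glutamate exchanger (chromosome 4, 138164097 to 138242349), was 8.62-fold higher (7.91 to 9.41), at 235 against 27.3 CPM. CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956519), was 8.24-fold higher (6.98 to 9.79). ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), was 7.66-fold higher (7.17 to 8.18), at 364 against 47.5 CPM. ALPP, placental alkaline phosphatase (chromosome 2, 232378534 to 232382889), was 31.2-fold lower (19.0 to 55.0), at 0.638 against 19.9 CPM. Its near-identical paralog ALPPL2 was 10.9-fold lower, and reads can be split between these genes. AFAP1L2, an actin filament-associated protein (chromosome 10, 114294824 to 114404756), was 24.1-fold lower (14.4 to 43.6), at 0.598 against 14.4 CPM. KRT7, a keratin of simple epithelia, was 6.34-fold lower, at 11.1 against 70.5 CPM.

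Of 15269 genes past the filter, 156 were at least 2-fold higher and 384 at least 2-fold lower in shID4, so that 71.1% of the 540 genes past the rule were lower. A total of 13090 genes (85.7%) differed by less than 1.5-fold, and the median log2 ratio of all 15269 genes was -0.02. Protein-coding genes made up 135 of the higher and 361 of the lower genes. The counts depend on the pseudocount, with 98 higher and 132 lower genes at 5 CPM and 256 and 633 at 0.1 CPM. Genes lower in shID4 had a median GC content of 56.3%, against 48.6% for genes higher in shID4 and 49.0% for all genes. Across genes, which are not independent replicates, the log2 ratio had a Spearman correlation of -0.36 with GC content and 0.05 with transcript length.

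**Figure D1:**
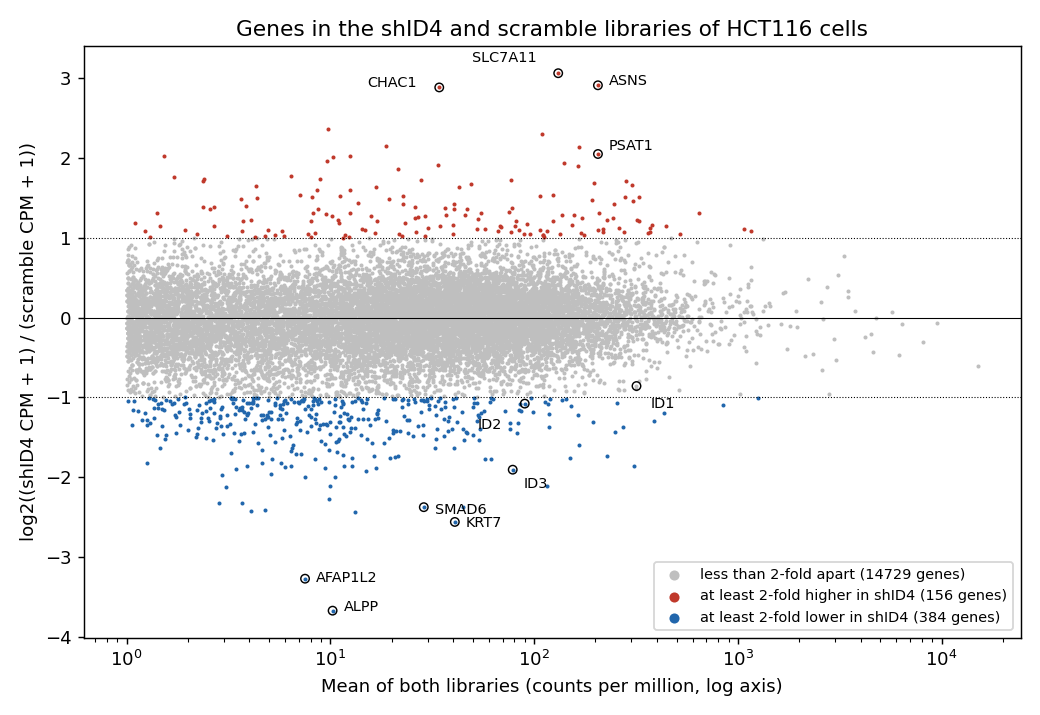
Each point is a gene past the filter of 1 CPM, with its mean over both libraries in CPM on a log axis and its log2 ratio of shID4 over scramble with a pseudocount of 1 CPM. Dotted lines mark the 2-fold rule, past which 156 genes lie above and 384 below; circled genes are named in the text.

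Among the other genes with the highest ratios, GPAT3, a glycerol-3-phosphate acyltransferase, was 5.04-fold higher, at 182 against 36.0 CPM. The neuropilin gene NRP1 was 4.98-fold higher. STC2, a secreted glycoprotein gene, and PSAT1, which encodes an enzyme of serine synthesis, were 4.46-fold and 4.18-fold higher. FGF9, a fibroblast growth factor, was 4.79-fold higher, and DCLK1, a kinase used as a tuft and stem cell marker, was 4.76-fold higher from 3.35 CPM. NT5E, the ecto-nucleotidase CD73, was 3.78-fold higher, at 259 against 68.6 CPM. UPP1, uridine phosphorylase, and SLC6A9, a glycine transporter, were 3.97-fold and 3.94-fold higher. C1orf116 was 4.92-fold higher. The long noncoding gene LUCAT1 was 6.82-fold higher, and as an antisense gene it can hold reads of a partner. Among the other genes with the lowest ratios, NGFR, a neurotrophin receptor, was 5.46-fold lower, at 13.8 against 75.6 CPM. MRC2, an endocytic collagen receptor, was 4.40-fold lower, at 42.8 against 188 CPM. The MHC class II gene HLA-DRB1 was 5.39-fold lower, with paralogs that can share its reads. ANK1, SAMD11, FOLR1, HMCN1, SLC4A8, PADI2 and PALM3 were between 4.27-fold and 6.72-fold lower.

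ATF4 target genes, listed for the integrated stress response, had the highest median of the 33 lists with at least 5 members past the filter. Of 24 members past the filter, 14 were at least 2-fold higher, 0 were 2-fold lower and 23 had a ratio above 0. The median log2 ratio was 1.08, above all 10000 matched random lists (percentile 100). The members with the largest ratios were SLC7A11, ASNS, CHAC1 and STC2. ATF4 itself, chosen after its value was seen, was 2.23-fold higher, at 523 against 234 CPM. CTH, chosen in the same way, was the single member below 0, at a log2 ratio of -0.37.

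Targets of the unfolded protein response of the endoplasmic reticulum had a median of 0.30 (percentile 99.9), with 16 of 20 members above 0. HSPA5, the chaperone BiP, was the single member past the rule, at 704 against 339 CPM (2.08-fold higher, 2.02 to 2.13), and its log2 ratio was 0.98, short of the rule, with the trend on GC content and length removed. CREB3L2 and HERPUD1 were 1.78-fold and 1.76-fold higher. The hypoxia list also had a median of 0.30 (percentile above 99.9), with 14 of 23 members above 0. NDRG1, a stress-responsive gene, was 2.86-fold higher, at 485 against 169 CPM, and VEGFA, a vascular growth factor, was 2.07-fold higher. The glucose transporter gene SLC2A3 was 2.35-fold lower. NRF2 targets had a median of 0.33 (percentile 99.9), with 13 of 19 members above 0. This list also holds SLC7A11. Thioredoxin reductase, TXNRD1, was 2.21-fold higher at 613 CPM, whereas the aldo-keto reductase AKR1C3 was 2.59-fold lower, with paralogs that can share its reads. The medians of these 3 lists were smaller under single alternatives, at 0.18 for the unfolded protein response with the trend on GC content and length removed, 0.15 for hypoxia with a pseudocount of 5 CPM and 0.18 for NRF2 targets without the filter, and each list still stood apart.

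BMP and TGF-beta targets had the lowest median of the 33 lists with at least 5 members, at -0.74, below all 10000 matched random lists (percentile 0). Of 22 members, 7 were at least 2-fold lower, 0 were 2-fold higher and 17 had a ratio below 0. ID1, ID2 and ID3 are members of this list. SMAD6, an inhibitor of BMP signalling (chromosome 15, 66702228 to 66782848), was 5.67-fold lower (4.90 to 6.60), at 8.62 against 48.9 CPM. ATOH8, a basic helix-loop-helix factor, was 12.2-fold lower (7.01 to 22.8), at 0.558 against 6.79 CPM. BMF, a pro-apoptotic BCL2 family gene, was 3.88-fold lower. MSX1, a homeobox gene chosen after its value was seen, was 2.71-fold lower, at 134 against 363 CPM. Without the 3 ID genes, the median of the other 19 members was -0.60 (percentile 0), and without all members that another list holds it was -0.37 (percentile 0.310).

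**Figure D2:**
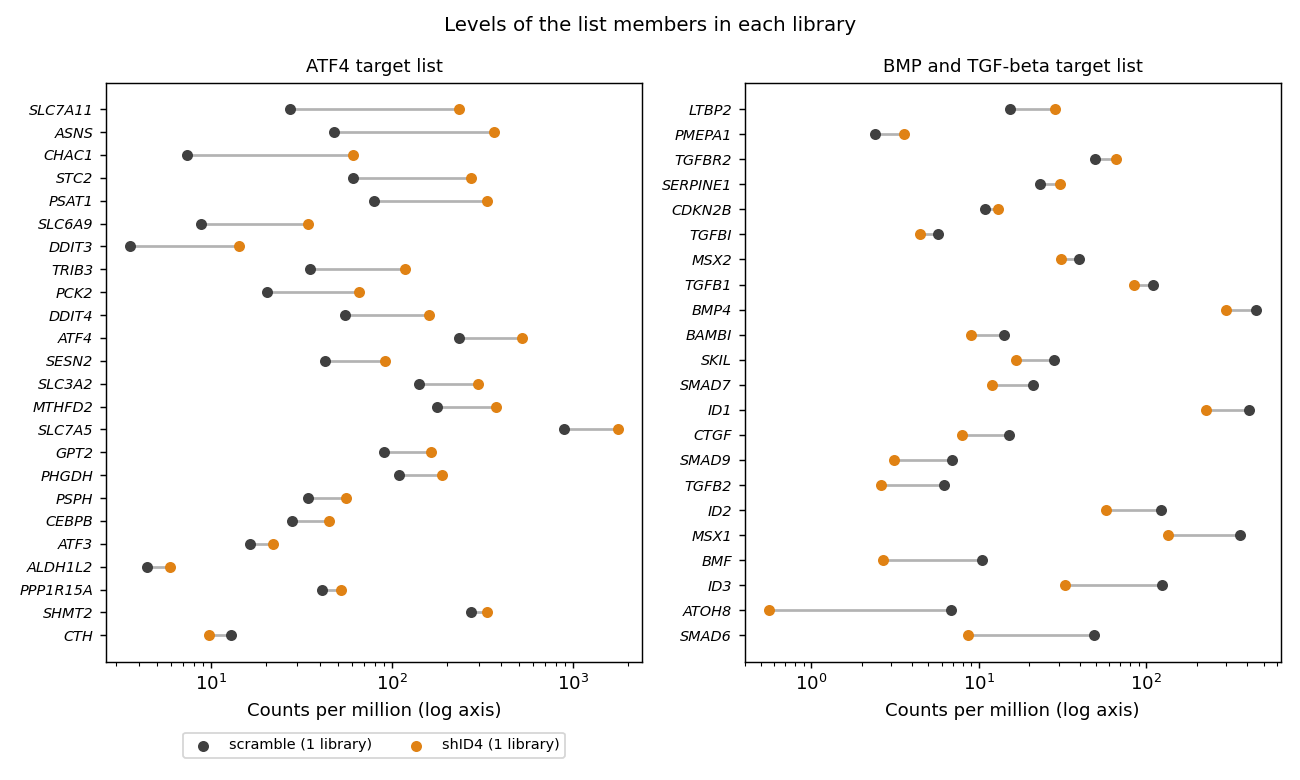
Each line is a gene of the ATF4 list or of the BMP and TGF-beta list past the filter, with its level in CPM on a log axis in the scramble library (dark) and the shID4 library (orange), 1 library each. Of the ATF4 targets, 23 of 24 were above 0 on the log2 scale, and of the BMP and TGF-beta targets, 17 of 22 were below 0.

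Targets of Wnt and beta-catenin had a median of -0.49 (percentile 0), with 13 of 18 members below 0, 4 at least 2-fold lower and 1 at least 2-fold higher. NOTUM, a secreted Wnt deacylase, was 3.25-fold lower, at 15.4 against 50.0 CPM. DKK1, a secreted Wnt antagonist, was 2.61-fold lower, at 65.3 against 171 CPM, and TNFRSF19 was 2.89-fold lower. FGF9 was the member past the rule in the other direction. Among targets chosen after their values were seen, AXIN2 had a log2 ratio of -0.87, MYC of 0.14 and CCND1 of 0.07. Without the filter the median of the Wnt list was -0.29 (percentile 0.0400). The Notch list had a median of -0.31 (percentile 0.330), with 14 of 18 members below 0. NOTCH3 was 1.91-fold lower, at 108 against 206 CPM, while HEY1, a target of the pathway, was 4.13-fold higher, at 4.15 CPM. With the trend on GC content and transcript length removed, the Notch median was -0.14 (percentile 10.3) and no longer stood apart.

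Interferon response genes had a median of -0.35 (percentile 0.0400), with 28 of 31 members below 0, of which 3 were at least 2-fold lower. These were IFIT1 at 3.37-fold lower, IFI6 2.84-fold and HERC5 2.81-fold, at 4.11, 5.03 and 10.7 CPM in shID4. IRF7, an interferon regulatory factor, was 1.94-fold lower. With a pseudocount of 5 CPM the interferon median was -0.23. Targets of p53 had a median of -0.19 (percentile 0.95), with 21 of 27 members below 0, and did not stand apart from random lists that were not matched on expression (percentile 2.885). CCNG1, cyclin G1, was 2.84-fold lower, at 26.1 against 74.0 CPM, and SESN2, which is also in the ATF4 list, was 2.14-fold higher. PMAIP1 was 1.91-fold higher and XPC 1.71-fold lower.

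Integrins and extracellular matrix receptors had a median of 0.19 (percentile 98.5), with 14 of 21 members above 0 and 3 past the rule. Among these, the laminin chain genes LAMA3 and LAMB3 were 3.29-fold and 2.10-fold higher. ITGB1 was 1.89-fold higher, at 1194 against 633 CPM. Stem and tumour-initiating cell markers had a median of 0.20 (percentile 97.7), with 10 of 14 members above 0. DCLK1 was past the rule, and ALDH1A3, PROM1 and ITGA6 were 1.93-fold, 1.88-fold and 1.85-fold higher. This list lay inside the random band under 5 of 10 alternatives, and the integrin list did so without the filter.

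Mitochondrially encoded transcripts took 7.38% of reads in scramble and 5.72% in shID4. Of 13 such genes, 12 were below 0, with a median of -0.31 (percentile 0.0950), and none reached 2-fold. MT-ND1 was 1.95-fold lower, at 1899 against 3697 CPM, and MT-CO1 was 1.52-fold lower. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.02 (percentile 36.5) and a mean of 0.00 of the opposite sign.

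**Figure D3:**
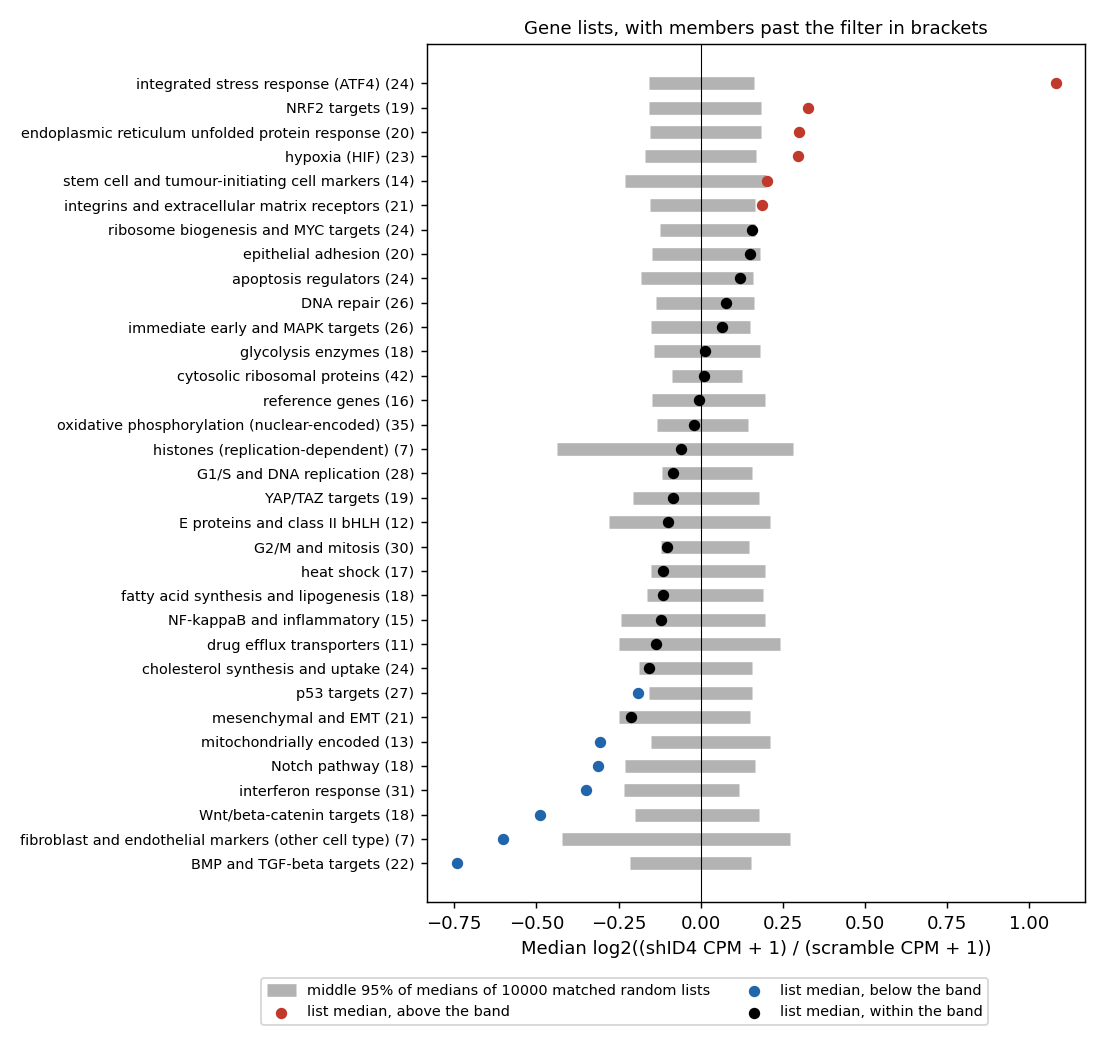
For each gene list with at least 5 members past the filter, the point is the median log2 ratio of shID4 over scramble with a pseudocount of 1 CPM, and the grey bar is the middle 95% of the medians of 10000 random lists matched on expression. Of 33 lists, 6 lie above and 7 below their bars, with ATF4 targets at 1.08 and BMP and TGF-beta targets at -0.74.

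The lists of proliferation, mesenchymal, adhesion, signalling, ribosome, metabolism and maintenance genes that follow lay inside the band of random lists. Proliferation genes had medians of -0.08 for G1/S (28 members, percentile 8.35) and -0.10 for G2/M (30 members, percentile 4.62). With the trend on GC content and length removed, the G2/M median was -0.21 and the list stood apart. CCNE2, cyclin E2, was the single proliferation gene past the rule, at 2.35-fold lower. Mesenchymal genes had a median of -0.21 (21 members, percentile 5.85), in which SPARC, a matrix glycoprotein, was 3.58-fold lower and SNAI2, a repressor of epithelial genes, was 4.48-fold higher from 1.58 CPM. The mesenchymal list stood apart under 4 alternatives, with a median of -0.42 among genes with a mean of at least 5 CPM. Epithelial adhesion genes had a median of 0.15 (20 members, percentile 94.7), and KRT18 was 1.95-fold lower at 695 CPM. Immediate early and MAPK targets had a median of 0.06 (26 members, percentile 81.7). In that list EREG and AREG, ligands of the EGF receptor, were 2.85-fold and 2.35-fold higher, FOSL1 was 2.70-fold higher and FOS 2.85-fold lower. NF-kappaB genes had a median of -0.12 (15 members, percentile 19.9), with ICAM1 2.53-fold and NFKBIA 2.27-fold lower. YAP and TAZ targets had a median of -0.08 (19 members, percentile 22.5), with NT5E past the rule upward and ANKRD1 and TGFB2 past it downward. TGFB2 did not reach the rule under centring or trimmed-mean scaling. With a pseudocount of 5 CPM, 11 genes chosen by the naming rule did not reach the 2-fold rule. These were AKR1C3, ANKRD1, CA2, CCNE2, HEY1, HLA-DRA, IFI6, SNAI2, TGFB2, TNFRSF19 and VEGFA. Genes named outside the naming rule, such as ALPPL2, are not in this count.

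Ribosome biogenesis genes had a median of 0.16 (24 members, percentile 96.9), with ODC1 1.91-fold higher, and cytosolic ribosomal proteins one of 0.01 (42 members, percentile 44.8). Glycolysis enzymes had a median of 0.01 (18 members, percentile 49.9), with ALDOC 2.48-fold lower and HK2 1.98-fold higher. Cholesterol synthesis genes had a median of -0.16 (24 members, percentile 4.87) and fatty acid synthesis genes one of -0.12 (18 members, percentile 8.25). Heat shock genes were at -0.12 (17 members, percentile 6.08), apoptosis regulators at 0.12 (24 members, percentile 92.6) and DNA repair genes at 0.08 (26 members, percentile 78.9). Drug efflux transporters were at -0.14 (11 members, percentile 12.8), and replication-dependent histones at -0.06 (7 members, percentile 52.4). The list of E proteins and other basic helix-loop-helix genes had a median of -0.10 (12 members, percentile 28.2) and a mean of 0.00. Among these members only TCF3, TCF4 and TCF12 are E proteins, and others are factors such as MYC, MAX and HES1. The median therefore does not describe the partners of ID proteins as a group. Reference genes had a median of 0.00 (16 members, percentile 39.4), with B2M and PGK1 within 1% of equality and ACTB 1.45-fold higher. With the trend on GC content and length removed, NF-kappaB, heat shock and ribosome biogenesis genes stood apart, and drug efflux transporters did so among genes with a mean of at least 5 CPM. Of colonic differentiation genes only 3 passed the filter, too few for a percentile, among which CA2, a carbonic anhydrase, was 2.11-fold lower and the median was -0.42.

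Fibroblast and endothelial markers had a median of -0.60 (7 members, percentile 0.350), with COL1A1 at 60.6 against 101 CPM and VWF at 0.918 against 1.91 CPM, and this list lay inside the band without the filter. Of immune markers 4 passed the filter, with a median of -0.27, HLA-DRA at 3.39 against 8.32 CPM and PTPRC at 1.91 against 2.06 CPM. Of kidney and hepatocyte markers, PAX2 and PAX8 passed the filter, with a median of -0.08.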

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

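The correction for GC content and transcript length and the omission of mitochondrially encoded genes or of shared list members were chosen after the data were seen. No paired analysis was possible because each group has 1 library. Numbers of genes depended on the settings of the size rule. There were 256 higher and 633 lower genes with a pseudocount of 0.1 CPM, 98 and 132 with 5 CPM, 778 and 1401 with a 1.5-fold rule, 11 and 15 with a 4-fold rule, and 252 lower genes among those with a mean of at least 5 CPM. These follow from the construction of each setting, since a larger pseudocount shrinks the ratios of low genes and a stricter filter removes them. The share of lower genes among all genes past the rule was smallest with a pseudocount of 5 CPM, at 57.4%. Centring and trimmed-mean scaling moved the counts to 160 and 376, and a common total moved nothing, because both columns already summed to 1000000. With the trend on GC content and length removed the counts were 158 and 309. Of the 13 lists that stood apart, Wnt, BMP and TGF-beta, interferon, ATF4, unfolded protein response, hypoxia, NRF2 and mitochondrially encoded genes did so under each alternative run on them. The p53 list did not with random lists not matched on expression (percentile 2.885), under which ribosome biogenesis genes came to stand apart. The stem cell list did not under 5 of 10 alternatives, the Notch list under removal of the trend or of shared members (percentile 3.19), and the integrin and fibroblast lists without the filter; the cause was not tested. Other lists came to stand apart: mesenchymal genes under 4 alternatives, drug efflux genes with a mean of at least 5 CPM, and G2/M (median -0.21), NF-kappaB, heat shock and ribosome biogenesis genes with the trend removed. With 5 CPM as pseudocount, 11 of the genes chosen by the naming rule no longer reached 2-fold, among them VEGFA, HEY1, SNAI2 and TGFB2. TGFB2 did not under centring or trimmed-mean scaling either. HSPA5 had a log2 ratio of 0.98 with the trend removed. The alternative on calls in the authors' table was not run, since that table holds values per library only. Depth limits genes with few reads such as ID4, whose log2 ratio was -0.43 with a pseudocount of 1 CPM and -1.27 with 0.1 CPM.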

Other observations

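The families of synthetases, one-carbon enzymes, hemidesmosome genes, MHC class II genes and keratins, the correction for GC content and length, and the test of a hairpin acting on ID1, ID2 and ID3, were chosen after the ranked genes had been seen. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, had 16 of 20 members above 0 and 7 at least 2-fold higher in shID4. Their median log2 ratio was 0.75 (percentile 100), and 0.71 without GARS, whose value had been seen first. GARS was 2.76-fold higher, at 451 against 164 CPM. YARS stood at 298 against 119 CPM, and WARS and AARS were 2.45-fold and 2.34-fold higher. Mitochondrial synthetases, encoded by separate nuclear genes, had a median of 0.08 (17 members, percentile 76.9) and 0 members past 2-fold. Enzymes of serine, glycine and one-carbon metabolism had a median of 0.34 (11 members, percentile 99.6), with PSAT1, MTHFD2 and MTHFD1L at least 2-fold higher, and 0.32 without PSAT1. Of these enzymes, 2 reached 2-fold with a pseudocount of 5 CPM, and 2 with the trend on GC content and length removed. Several of these enzymes, among them PSAT1 and MTHFD2, are also ATF4 list members, so this family is not separate from that list. Genes of the hemidesmosome and its laminin, the anchor of epithelial cells to the basement membrane, had a median of 0.77 (9 members, percentile above 99.9), and 0.64 without the members seen first, with 1 of the other 7 at least 2-fold higher. Several of them are also in the integrin list. PLEC, plectin, stood at 4184 against 2448 CPM and ITGB4 at 1408 against 904 CPM, while CD151 was lower, at a log2 ratio of -0.86.

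MHC class II genes had 7 of 10 members at least 2-fold lower in shID4, from low levels, with a median of -1.17 (percentile 0) and -1.14 without HLA-DRB1. HLA-DPB1 stood at 0.798 against 4.11 CPM and HLA-DMB at 2.99 against 8.32 CPM. CIITA, the activator of these genes, stood at 3.19 against 2.68 CPM, with an interval of the ratio from 0.837 to 1.71. With a pseudocount of 5 CPM the median was -0.59 and 1 gene passed 2-fold, and reads can be split between these similar genes. A list of keratins had a median of -0.81 (8 members, percentile 0), and -0.65 without KRT7, which had been seen first. KRT7 and the hair keratins KRT81 and KRT86 were at least 2-fold lower. Without the hair keratins, the other 6 members, keratins of epithelia, had a median of -0.57, below the random band from -0.31 to 0.32. Of these KRT7 alone was past 2-fold, with KRT8 at 2011 against 3158 CPM and KRT19 above 0 at 0.28. Without KRT7 as well, the other 5 had a median of -0.49 (percentile 0.41), and 0 of them were past 2-fold. With a pseudocount of 5 CPM the median of all 8 keratins was -0.51 and 1 of them passed 2-fold. With the trend on GC content and length removed, the keratin median was -0.67, with 2 members past 2-fold, and the MHC class II median -1.21.

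More genes were lower than higher by the 2-fold rule, 384 against 156. The share of lower genes was 57.4% with a pseudocount of 5 CPM. Under centring and trimmed-mean scaling it was 70.1% (Wilson interval 66.1% to 73.9%), where 60% or less was predicted if scaling were the cause. Each of these settings moved the median log2 ratio by only 0.007, which left the share little room to fall. Provided that most genes are unchanged, this argues against a scaling error. A change in most genes at once would escape these settings. The Wilson intervals given here treat genes as independent, which they are not, and can be too narrow. Removal of the trend on GC content and transcript length left 66.2% of 467 genes lower (61.8% to 70.3%), against 71.1% before. That interval spans the limit of 65% set for the test, so a GC or length bias in library preparation may account for part of the imbalance, and it cannot be told apart from an effect of the hairpin because each group has 1 library.

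ATF4 targets were higher in shID4, with a median of 1.08. A bias by GC content or length was argued against, since the median was 1.26 with the trend removed (0.86 to 1.85 over resampled members). Intervals over resampled members, here and below, cover the spread among the genes of a list. They do not cover variation between cultures. A candidate explanation is ATF4 activity, which should reach known targets outside the list. The median of cytosolic synthetases exceeded that of mitochondrial synthetases by 0.67, where at least 0.3 was predicted. These families were listed after GARS had been seen in the same libraries, so they are not an independent check. Without GARS the cytosolic median was 0.71, against 0.08 for mitochondrial synthetases. NRF2 activity stays open as a contributor, since NRF2 targets in no other list had a median of 0.33 (-0.08 to 0.57), an interval that spans the limit of 0.54. Whether loss of ID4, another effect of the hairpin or a difference between the cultures, such as amino acid supply, lies behind it was not tested.

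ID genes and other BMP targets were lower in shID4. A hairpin acting on the similar ID1, ID2 and ID3 transcripts stays open, because the 19 targets that are not ID genes, with a median of -0.60 at percentile 0 of random lists, could also be lower as a consequence of lower ID genes. A GC or length bias was not settled by its test. With the trend removed the median was -0.65 (-1.04 to -0.29 over resampled members). That interval spans the limit of -0.5 and also just passes the upper limit set for the test. It still lies below the middle 95% of random lists (-0.20 to 0.14), so the list stood apart with the trend removed. BMP2, BMP4 and BMP7 summed to 311 CPM against 469 CPM, a log2 ratio of -0.59 (-0.64 to -0.55) that lies between the limits set for the test. BMP4 gave most of this sum, at 298 CPM in shID4 against 452 CPM in scramble, and is itself a member of the BMP and TGF-beta list. The sum is therefore not separate from the pattern, and it cannot tell whether lower ligand expression contributes. Of these ligands BMP4 and BMP7 passed the filter, with a median of -0.48, and weaker BMP signalling after loss of ID4 remains a hypothesis that 1 library per group cannot test.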
